A study of Homo sapiens with 4 samples.

How the data were processed

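Messenger RNA levels were measured in 4 libraries of A375 cells, an established human melanoma line that carries an activating BRAF mutation. Per the labels' protocols, the cells were kept for 6 h in medium with 0.01% olive oil or 0.01% ozonated olive oil, RNA was taken with Tri reagent, and libraries were made with a directional kit. The titles number the libraries of each group 1 and 2. The labels do not say whether the libraries come from separate cultures or days, so p-values of single genes measure the spread between these libraries, which may be technical.

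The deposited table holds raw counts, whole numbers that sum to a different total in each library, with 1 column per library and 28395 rows keyed by Entrez gene ID, Ensembl ID and symbol. Per the submitters' processing notes, which give tools with no role or order, bcl2fastq, FastQC 0.11.7, HISAT2 2.1.0, StringTie 1.3.4d, SAMtools 1.9, bedtools 2.27.1 and edgeR were used with the human build hg38. The counting tool, its strand setting and the annotation are not given in the sources used here, so reads of a gene and of its antisense partner may not be separated. Reads shared with a near-identical copy may have been dropped or split. Rows without a symbol numbered 617 and held 0.042% to 0.049% of the counts. They were kept, since each has a gene ID.

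Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group, library sizes were scaled by TMM (factors from 0.972 to 1.017), and the groups were compared by edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. No block was used. CPM values use the TMM-scaled library sizes. Standard errors of log2 fold changes were derived from the fitted value and its F statistic. Because the libraries split by their replicate number, differences between the oils within each number (1 library against 1, log2 CPM with a prior count of 2) are given beside the fitted values. They carry no test. With 2 libraries per group the smallest two-sided exact permutation p for a single value is 0.333, so the text relies on the model fitted across genes.

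Before the data were examined, 39 gene lists with 1271 entries were written from textbook knowledge. Of these entries, 1255 matched by symbol and 16 by a RefSeq synonym. Lists with at least 5 tested members (37 lists) were compared with all other genes by camera of limma 3.58.1, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over lists. The rule for named genes, fixed at the same time, had 3 parts. The first took the 12 genes with the largest rise and the 12 with the largest fall among those past the test, and no gene met it. The second took up to 4 members with the smallest p and up to 2 members of highest level from each described list. The third took 25 genes whatever their values. Described are the 10 lists with the smallest p. After no gene passed, a further rule was added with the data in view: the 12 genes each way with the largest difference shared by both replicate numbers, at an average log2 CPM of 2 or more.

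Coordinates are those of RefSeq on GRCh38.p14, the same build as hg38. For tests of GC content and length, the longest transcript of each gene in the GENCODE annotation was used, which covered 97.6% of the tested genes. Each library's deviation from the mean was fitted on both properties with splines (mgcv) and taken into the edgeR offsets. Alternatives were other scalings, other filters, DESeq2 1.42.0, limma-voom, the edgeR exact test, the replicate number as a block, a minimum fold and each library left out in turn. Lists were also tested with an estimated correlation and with fry. Block versions of DESeq2, limma-voom, fry and the estimated correlation were added after the data were seen, as was the test of the replicate number itself. Where a library is left out, its group has 1 library, which is assumed to vary like the other group.

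The test was run on simulated data, with counts drawn for 14841 genes from the real means and library sizes and 200 genes changed. Dispersions came from the fit with the replicate number as a block, and any difference between the numbers was the same for both oils. The block is therefore the true model in that simulation, and its recovery is a best case. With the difference between the replicate numbers kept in the simulation, the fit without a block recovered 0% of genes changed 2-fold and 51.0% of those changed 4-fold, and with the replicate number as a block 79.0% and 94.5% on the same counts (11 and 18 false calls, against 0 and 0 without it). With that difference left out, it recovered 78.5% and 93.5%. Library totals ranged from 22245807 to 27772480 counts. A count of 0 in a library allows a level of up to 0.108 to 0.135 CPM (3 counts of the total), which covers counting error only, since no molecular identifiers are named.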

Results

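The series compared A375 human melanoma cells after 6 h with 0.01% olive oil and after 6 h with 0.01% ozonated olive oil, which carries ozonides and peroxides formed on the unsaturated fatty acids of the oil. Each group had 2 libraries, numbered 1 and 2. Total counts were 27772480 and 26609495 in the olive oil libraries and 23571726 and 22245807 in the ozonated olive oil libraries. Mitochondrial genes took 2.0% to 2.4% of the counts, and the 10 most abundant genes 4.2% to 4.8%. The libraries numbered 1 and those numbered 2 stood apart in both groups: the first principal component (66.4% of the variance) separated the numbers, and the second (21.3%) separated the oils. The SD of log2 differences over genes was 0.41 and 0.47 between libraries of the same number and 0.66 and 0.69 between libraries of the same oil. Counts of each pair of libraries differed by more than sampling noise (chi-square per degree of freedom from 22.8 to 66.3).

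**Figure D1:**
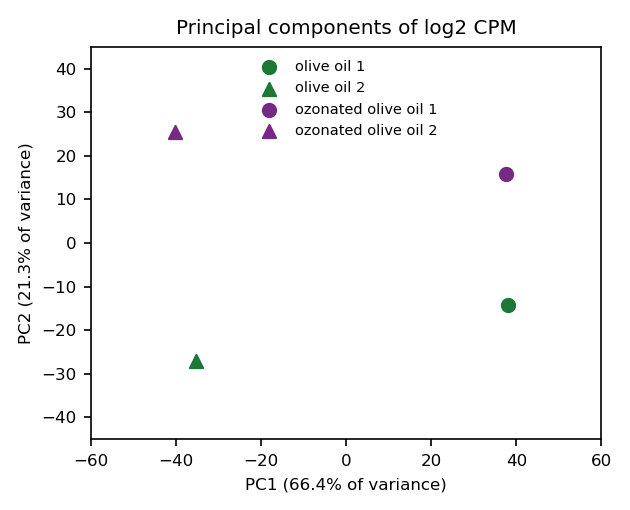
Principal components of log2 CPM over the tested genes, with 1 point per library (colour for the oil, shape for the replicate number). PC1 (66.4% of the variance) runs from 38.1 in olive oil 1 to -40.2 in ozonated olive oil 2 and separates the numbers, and PC2 (21.3%) separates the oils.

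The comparison of the oils asked which transcripts differ after the ozonated oil. Targets of HIF, the transcription factor of the hypoxia response, rose relative to all other genes: 36 of 38 tested members were higher within both replicate numbers, with a median log2 fold change of 0.61 (camera with a preset correlation; adjusted p = 0.647 with an estimated one). Targets of NRF2, the factor that answers electrophiles and oxidants, also rose, with 34 of 39 members higher within both numbers and a median of 0.41 (adjusted p = 0.302 with an estimated correlation). Genes of the actin cytoskeleton and targets of SRF or YAP fell, with 20 of 29 members lower within both numbers and a median of -0.30 (adjusted p = 0.309 with an estimated correlation). Among single genes, HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1, lay at 59.1 ± 28.7 CPM (SD, n = 2) with olive oil and 696.5 ± 493.6 CPM (SD, n = 2) with the ozonated oil. The YAP target AMOTL2 lay at 210.7 ± 15.1 CPM (SD, n = 2) and 84.7 ± 6.18 CPM (SD, n = 2).

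By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 14841 tested genes differed between the oils (smallest adjusted p = 0.748), and 570 had an unadjusted p under 0.05 where chance gives 742. In simulated data with the difference between the numbers kept, this fit recovered 0% of genes changed 2-fold. The count of 0 therefore does not show that the oils act alike. On the 4 real libraries DESeq2 called 58 genes (38 higher, 20 lower), the edgeR exact test 35 (22 higher, 13 lower) and limma-voom 0. With the replicate number as a block, a pairing that the labels do not give, edgeR called many more, as stated with the alternatives below. Both ozonated libraries lay above both olive oil libraries for 2266 genes and below them for 2336, or 31.0% of the tested genes. Chance gives 33.3% for 4 interchangeable libraries. The split by number within each oil makes such genes, and p under 0.05, rarer without any effect of the oil. Neither the 31.0% nor the 570 therefore shows that the oils differ no more than by chance. Within the replicate numbers, 50 genes were at least 2-fold higher in both and 78 at least 2-fold lower in both, where independent differences would give 4.78 and 7.48. Another 43 genes differed 2-fold in opposite directions, where independence gives 12.2. Over all tested genes the differences within number 1 and within number 2 correlated with r = 0.233 (Spearman 0.307). Over the 11083 genes with an average log2 CPM of 2 or more, r was 0.448 (Spearman 0.443). These are values across genes, which are not independent replicates. Without olive oil replicate 1 the test called 1 gene, SLC25A6 (log2 fold change -7.34), whose counts of 6, 3030, 13 and 18 stand in a region of erratic counts. Without ozonated olive oil replicate 1 it called 4 genes, all higher: EGR1 (4.06), FOS (4.86), INSIG1 (2.58) and JUN (2.64). SLC25A6, INSIG1 and JUN are named only after their values were seen. Here and below, leaving out a library leaves the numbers unequal between the oils, so the fit then mixes the oil with the number.

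Gene lists were compared with all other genes by camera with a preset correlation of 0.01. With the correlation preset, its p-values take genes as the units and rest on the spread between genes, not between libraries. A small p-value there does not show that a list would differ again in other libraries. Of 37 lists tested, 20 passed (15 up, 5 down), and 0 passed with an estimated correlation, where the smallest adjusted p was 0.302. The estimate was 0.475 for HIF targets, but 0.0023 for NRF2 targets and -0.016 for thioredoxin-interacting and glucose sensing genes (glucose sensing genes below), both below the preset 0.01. For NRF2 targets and glucose sensing genes, a higher correlation is thus not what lost the call. That version rests on the few residual degrees of freedom of 4 libraries, so a lost call there does not show that a list is unchanged. With fry 0 passed (smallest adjusted p = 0.27). Leaving out each of the 4 libraries in turn, 5 of the 20 lists stayed past the threshold in the same direction throughout: HIF targets, NRF2 targets, the actin list, glucose sensing genes and heat shock genes. The other 15 lost the call or the direction without at least 1 library, which the mixing of oil and number can also bring about.

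**Figure D2:**
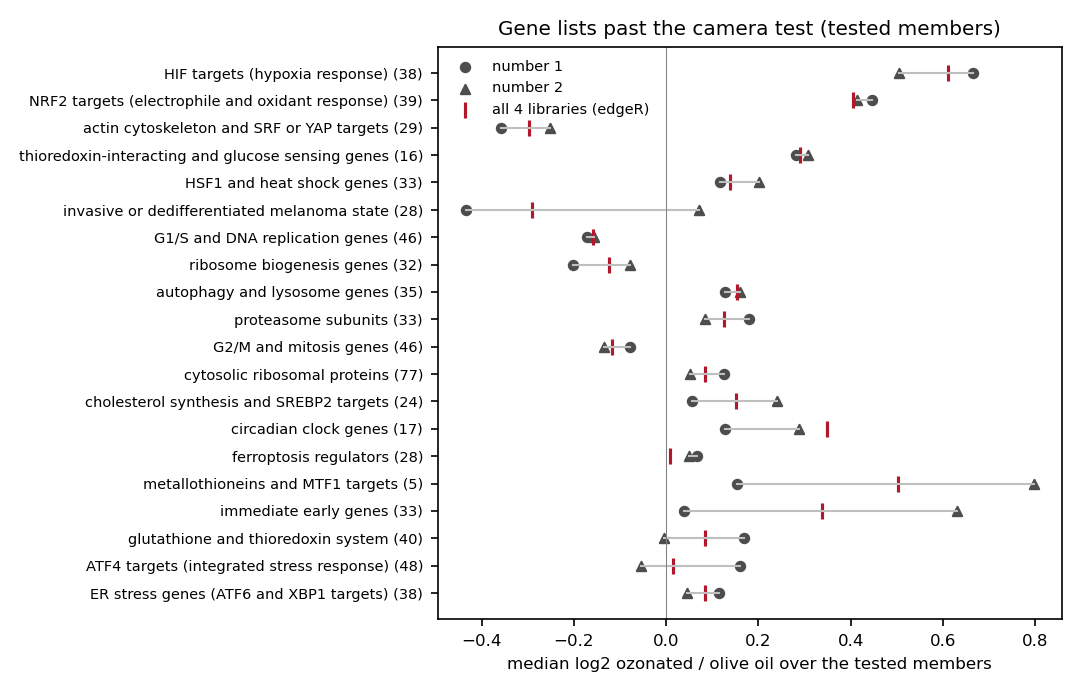
Median log2 ratio of ozonated to olive oil over the tested members of the 20 lists past the camera test, within replicate number 1 (circles), within number 2 (triangles) and in the fit to all 4 libraries (red bars). HIF targets have medians of 0.67 and 0.50 within the numbers, NRF2 targets 0.45 and 0.41, and the actin list -0.36 and -0.25, while the invasive state list lies at -0.43 and 0.07.

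The HIF target list had a camera adjusted p of 3.48e-28, and an adjusted p of 0.647 with an estimated correlation. Within-number medians were 0.67 and 0.50. No member passed over all genes, and 6 passed adjusted over the list alone: SLC2A3, KDM3A, PDK1, HK2, MXI1 and ANKRD37. Here and below, that adjustment covers the members of a list only and makes no allowance for the number of lists. SLC2A3 (ENSG00000059804, chromosome 12, 7919230 to 7936187, GRCh38), which encodes the glucose transporter GLUT3 and has the close copy SLC2A14, had a log2 fold change of 1.87 ± 0.20 (SE) and within-number values of 1.54 and 2.15. KDM3A, a histone demethylase, had 1.22 ± 0.17, PDK1, the kinase that restrains pyruvate dehydrogenase, 1.20 ± 0.18, and the hexokinase HK2 0.80 ± 0.13. NDRG1 lay at 212 and 81.8 CPM in the olive oil libraries and at 669 and 212 CPM in the ozonated ones, and the carbonic anhydrase gene CA9 at 35.1 and 1.04 CPM against 89.0 and 8.23 CPM. NDRG1 had a value of 1.58, and 0.53 without ozonated olive oil replicate 1. CA9 differed more between the numbers than between the oils, and its fitted value of 1.43 became -1.14 without ozonated olive oil replicate 1. Its within-number values were 1.34 and 2.89. The glycolytic enzymes ENO1 and LDHA, the most abundant members, had values of 0.21 ± 0.11 and 0.42 ± 0.29. Levels of this list also differed between the replicate numbers of each oil, with medians of -0.44 (olive oil) and -0.47 (ozonated oil) in number 2 against number 1.

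The NRF2 target list had a camera adjusted p of 3.74e-21, and an adjusted p of 0.302 with an estimated correlation. Within-number medians were 0.45 and 0.41. Adjusted over the list alone, 4 of 39 members rose: HMOX1, SQSTM1, MAFG and TRIM16. HMOX1 (ENSG00000100292, chromosome 22, 35381096 to 35394207, GRCh38) had a log2 fold change of 3.56 ± 0.66 (SE, unadjusted p = 0.0031 by edgeR, not past the adjusted threshold over all genes) and within-number values of 3.16 and 3.72, so that it was 8.93-fold and 13.2-fold higher. SQSTM1, the autophagy receptor p62, had 0.90 ± 0.15, MAFG, a partner of NRF2 on DNA, 0.53 ± 0.10, and TRIM16, which has the near copy TRIM16L, 0.54 ± 0.11. GCLM, a subunit of the enzyme that limits glutathione synthesis, had 0.66 ± 0.15, the cystine transporter gene SLC7A11 0.80 ± 0.42 (within-number values 1.19 and 0.59) and the thioredoxin reductase gene TXNRD1 0.52 ± 0.24, none past the test. SLC7A11 had 0.33 without olive oil replicate 1, 1.5 without olive oil replicate 2 and 0.49 without ozonated olive oil replicate 2. The ferritin genes FTH1 and FTL, which have many processed pseudogenes, had 0.59 ± 0.16 and 0.67 ± 0.24, with 0.32 for FTL without ozonated olive oil replicate 2. NQO1, a quinone reductase and standard marker of this response, had 0.27 ± 0.43 with within-number values of 0.40 and 0.20. Its fitted value became -0.16 without olive oil replicate 1 and -0.21 without ozonated olive oil replicate 2.

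The list of actin cytoskeleton genes and SRF or YAP targets had a camera adjusted p of 1.28e-17, and an adjusted p of 0.309 with an estimated correlation. Within-number medians were -0.36 and -0.25. Adjusted over the list alone, 4 of 29 members fell: AMOTL2, AJUBA, CCN1 and CCN2. AMOTL2 (ENSG00000114019, chromosome 3, 134355345 to 134375417, GRCh38) had a log2 fold change of -1.31 ± 0.12 (SE) and within-number values of -1.31 and -1.32. AJUBA, a LIM protein of cell junctions, had -1.0 ± 0.11, and the secreted matricellular proteins CCN2 and CCN1 had -1.60 ± 0.22 and -1.56 ± 0.29. ANKRD1, another YAP target, lay at 72.6 and 30.7 CPM with olive oil and at 15.3 and 7.49 CPM with the ozonated oil, a value of -2.18 that was -1.43 without olive oil replicate 1. The actin genes ACTB and ACTG1, the most abundant members, had -0.32 ± 0.10 and -0.27 ± 0.12.

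**Figure D3:**
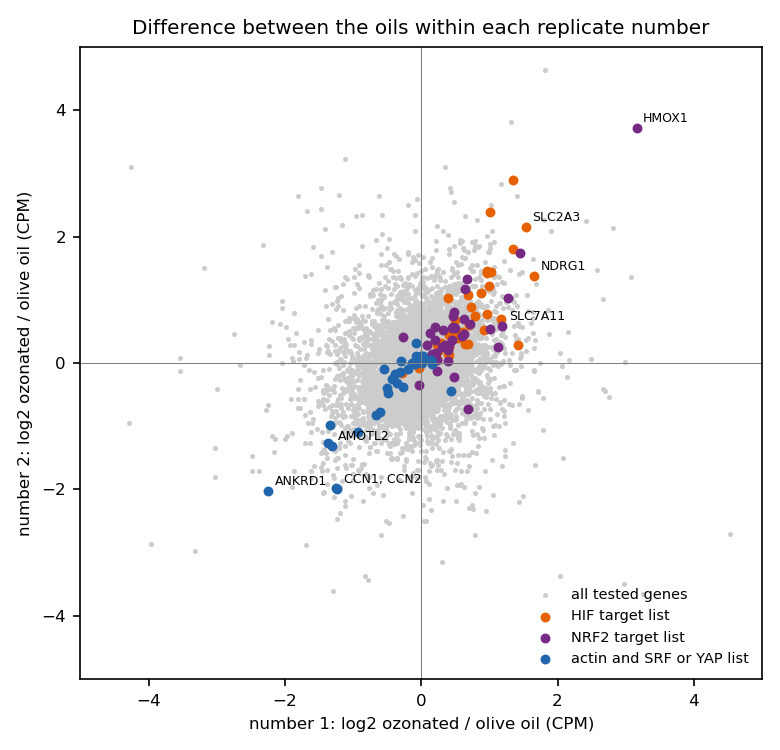
Log2 ratio of ozonated to olive oil within replicate number 1 (x axis) and within number 2 (y axis) for all tested genes (grey) and the members of 3 lists (colours), from log2 CPM, with 1 library against 1 on each axis and 4 genes outside the axis limits. HMOX1 lies at 3.16 and 3.72 and AMOTL2 at -1.31 and -1.32.

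The list of thioredoxin-interacting and glucose sensing genes (16 tested, 4 of them also in the HIF list) rose, with a median of 0.29. Within-number medians were 0.28 and 0.31, and the camera adjusted p was 1.03e-08 (adjusted p = 0.309 with an estimated correlation). TXNIP had 0.17 ± 0.35, with within-number values of 0.78 and -0.27. The members named next encode a glucose transporter and glycolytic enzymes. SLC2A3 and HK2 passed adjusted over the list alone, HK1 had 0.41 ± 0.12 and PFKL 0.32 ± 0.17, and the most abundant members PKM and LDHA had 0.19 ± 0.14 and 0.42 ± 0.29. HSF1 and heat shock genes (33 tested) rose, with a median of 0.14, within-number medians of 0.12 and 0.20 and a camera adjusted p of 1.55e-08 (adjusted p = 0.651 with an estimated correlation). The co-chaperones BAG3 and DNAJB4 had 0.44 ± 0.10 and 0.89 ± 0.27, and the abundant chaperones HSPA8 and HSP90AA1 0.52 ± 0.25 and 0.35 ± 0.13. DNAJB1 had 0.92 ± 0.36, with 0.35 within number 1 and 1.29 within number 2, and 0.29 without ozonated olive oil replicate 2. HSPA1A was not tested (1, 0, 0 and 3 counts) and stands in a region where nearly all genes have few counts.

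Genes of the invasive, dedifferentiated melanoma state (28 tested, 6 of them also in the actin list) fell in the pooled fit, with a median of -0.29 and a camera adjusted p of 3.31e-07 (adjusted p = 0.666 with an estimated correlation). The within-number medians were -0.43 and 0.07, and the call was lost without olive oil replicate 1 (adjusted p = 0.0564). AMOTL2, CCN1 and CCN2 passed adjusted over the list alone, and the matrix protein gene THBS1 had -1.11 ± 0.26 (-0.72 without olive oil replicate 1), while the abundant members VIM and SPARC had 0.21 ± 0.10 and 0.08 ± 0.13. The value of SPARC became -0.01 without olive oil replicate 2 and -0.02 without ozonated olive oil replicate 1.

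Genes of G1/S and DNA replication fell by little, with a median of -0.16 over 46 members, 38 of them lower within both numbers (within-number medians -0.17 and -0.16). The camera adjusted p was 9.06e-07 (adjusted p = 0.72 with an estimated correlation), and the call was lost without olive oil replicate 2 (adjusted p = 0.234) and without ozonated olive oil replicate 1 (adjusted p = 0.214). UHRF1 had -0.36 ± 0.12, CDC6 -0.31 ± 0.11, MCM10 -0.27 ± 0.11 and CLSPN -0.27 ± 0.12. The abundant members MCM7 (-0.08 ± 0.16) and RRM2 (-0.01 ± 0.18) turned to 0.05 and 0.14 without olive oil replicate 2 and to 0.06 and 0.16 without ozonated olive oil replicate 1. Ribosome biogenesis genes (32 tested) fell, with a median of -0.12, within-number medians of -0.20 and -0.08 and a camera adjusted p of 1.64e-06 (adjusted p = 0.72 with an estimated correlation; 0.208 with the preset one without ozonated olive oil replicate 1). In this list MYC had -1.0 ± 0.25, RRS1 -0.55 ± 0.11, UTP15 -0.41 ± 0.11, POLR1C -0.34 ± 0.11 and NCL -0.10 ± 0.10. NPM1, at 0.05 ± 0.19, turned to -0.11 without olive oil replicate 1 and -0.15 without ozonated olive oil replicate 2.

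Autophagy and lysosome genes (35 tested) rose, with a median of 0.15, within-number medians of 0.13 and 0.16 and a camera adjusted p of 2.94e-06 (adjusted p = 0.72 with an estimated correlation). The call was lost without olive oil replicate 2 (adjusted p = 0.0817) and without ozonated olive oil replicate 1 (adjusted p = 0.194). GABARAPL1, a membrane anchor of autophagosomes, and SQSTM1 passed adjusted over the list alone, with 1.20 ± 0.17 and 0.90 ± 0.15. ULK1 had 0.42 ± 0.15, the lysosomal enzyme gene GLA 0.48 ± 0.15, LAMP1 0.11 ± 0.10 and CTSB 0.22 ± 0.25, which turned to -0.09 without ozonated olive oil replicate 1. Proteasome subunits (33 tested) rose, with a median of 0.12, within-number medians of 0.18 and 0.08 and a camera adjusted p of 9.86e-05 (adjusted p = 0.666 with an estimated correlation). That call was lost without ozonated olive oil replicate 1 (adjusted p = 0.0817). PSMB7 had 0.30 ± 0.11, PSMC4 0.21 ± 0.10, PSMD11 0.21 ± 0.10, PSME4 0.27 ± 0.13 and PSMB4 0.05 ± 0.10. PSMD2, at 0.11 ± 0.27, turned to -0.15 without olive oil replicate 2 and -0.18 without ozonated olive oil replicate 1.

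The other 10 lists past the camera test had medians from -0.12 to 0.50, and all lost their call with an estimated correlation (adjusted p from 0.608 to 0.855) and without at least 1 library. G2/M and mitosis genes fell (median -0.12). Cytosolic ribosomal proteins (0.08), cholesterol synthesis genes (0.15), circadian clock genes (0.35), immediate early genes (0.34) and ER stress genes (0.08) rose. Ferroptosis regulators, glutathione and thioredoxin genes and ATF4 targets passed upward by camera with mixed members, as did the list of metallothioneins and MTF1 targets (3 of 5 tested members higher, median 0.50, within-number medians 0.15 and 0.80). Of the ferroptosis regulators 14 were higher and 14 lower (median 0.01), of the ATF4 targets 27 were higher and 21 lower (median 0.01, within-number medians 0.16 and -0.05), and the glutathione list had a median of 0.08 with within-number medians of 0.17 and -0.01. Without olive oil replicate 1, the fitted direction of ATF4 targets turned down, and that of ribosomal proteins did so in sign only. ATF4 targets also turned down without ozonated olive oil replicate 2. Olive oil is then number 2 alone in the first case, and the ozonated oil number 1 alone in the second. In number 2, 38 of 48 ATF4 targets were called higher, so these turns cannot be assigned to the oil. Immediate early genes moved apart: FOS and EGR1 had 4.0 ± 1.10 and 3.23 ± 0.997 while MYC, CCN1 and CCN2 of the same list had negative values. Both were higher in number 2 than in number 1 after the ozonated oil, with FOS at 13.2 and 125 CPM against 3.68 and 4.94 CPM with olive oil and EGR1 at 58.2 and 475 CPM against 23.3 and 33.6 CPM. Without ozonated olive oil replicate 2 the list had an adjusted p of 0.954, and FOS and EGR1 had 1.62 and 1.03.

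Of the lists tested, 17 did not pass (adjusted p from 0.0718 to 0.89), among them p53 targets, interferon-stimulated genes, NF-kB targets, apoptosis regulators, nuclear oxidative phosphorylation subunits and the melanocyte lineage. In the list of PPAR targets and lipid droplet genes (29 tested, median 0.05, adjusted p = 0.0718), PLIN2, which coats lipid droplets, and ANGPTL4, an inhibitor of lipoprotein lipase, rose when adjusted over the list alone. PLIN2 lay at 463 ± 15.5 CPM (SD, n = 2) with olive oil and 1102 ± 190 CPM (SD, n = 2) with the ozonated oil, and ANGPTL4 at 33.6 ± 3.97 CPM (SD, n = 2) and 71.7 ± 6.41 CPM (SD, n = 2). Adjusted over the list alone, AHR was higher among AHR targets (0.53), and CCN2 lower among immediate early genes and among TGF-beta targets (-1.60). These calls make no allowance for the number of lists, and neither gene passed over all genes. NF-kB targets had within-number medians of -0.57 and 0.52. Markers of keratinocytes and fibroblasts had medians of -0.03 and 0.11 (adjusted p = 0.87 and 0.669), and 4 leukocyte and 2 endothelial or blood markers were too few to test. The median and the test differed in sign for TGF-beta targets (median 0.05, lower by camera), histones (-0.07, higher), and detoxification of reactive oxygen (0.02, lower), and for the melanocyte lineage the mean did (-0.09, against a median of 0.04).

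**Figure D4:**
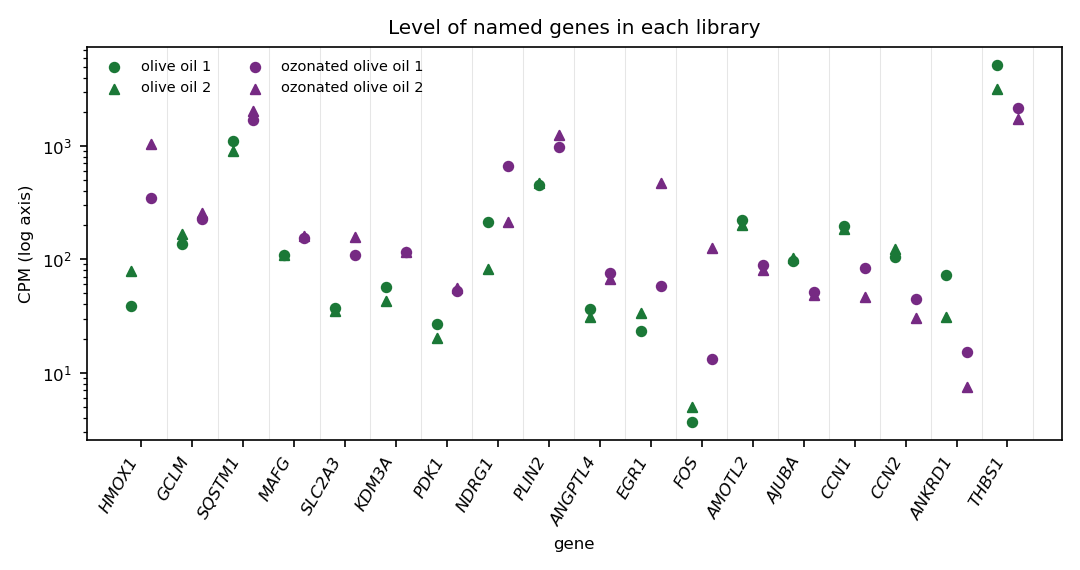
CPM of 18 named genes in each of the 4 libraries on a log axis, with olive oil in green, ozonated olive oil in purple, replicate number 1 as circles and number 2 as triangles. For HMOX1 the olive oil libraries lie at 38.8 and 79.4 CPM and the ozonated ones at 347 and 1046 CPM, and for AMOTL2 at 221 and 200 CPM against 89.1 and 80.3 CPM.

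Of the other genes fixed in advance, ATF3, DDIT3 and MT2A had log2 fold changes of 1.09 ± 0.40, 0.51 ± 0.27 and 0.50 ± 0.21, and CCNB1, MKI67, MITF, DUSP6 and GPX4 had -0.29 ± 0.11, -0.13 ± 0.11, -0.33 ± 0.22, -0.26 ± 0.20 and 0.09 ± 0.12. ATF3 had 0.21 within number 1 and 1.79 within number 2 (0.43 without ozonated olive oil replicate 2), and DUSP6 0.11 and -0.65. The values of CXCL8 (-0.88 ± 1.28), CHAC1 (-0.69 ± 0.83), CDKN1A (0.33 ± 0.76), TXNIP (0.17 ± 0.35), HMGCS1 (0.16 ± 0.24) and HSPA5 (-0.03 ± 0.12) turned in sign with 1 library left out. CXCL8 turned to 2.67 and TXNIP to -0.25 without olive oil replicate 1, and CHAC1 turned to 1.05 without olive oil replicate 2. CDKN1A turned to -0.33 without olive oil replicate 2 and to -0.62 without ozonated olive oil replicate 1. Without ozonated olive oil replicate 2, HMGCS1 turned to -0.23 and HSPA5 to 0.08. CXCL8, a cytokine gene, lay at 269 and 12 CPM with olive oil and at 100 and 52.5 CPM with the ozonated oil, with within-number values of -1.42 and 2.12.

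Genes chosen after their values were seen, for the largest difference shared by both numbers, included OSGIN1, an NRF2 target (1.65 ± 0.47, within-number values 1.45 and 1.74), CCNG2 (1.46 ± 0.24, 1.47 and 1.44), PNRC1 (1.64 ± 0.33, 1.64 and 1.64), the pseudogene NMRAL2P (1.87 ± 0.52, 2.58 and 1.47), PPFIA4 (1.51 ± 0.28, 1.68 and 1.26) and the nuclear receptor gene NR4A2 (2.20 ± 1.11, 1.80 and 2.26), which had 0.284 without ozonated olive oil replicate 2. Lower in both numbers were ADAMTS6 (-1.46 ± 0.24), PRICKLE1 (-1.58 ± 0.27), SMAD6 (-1.40 ± 0.39), FAM222A (-1.28 ± 0.24), RIN2 (-1.20 ± 0.32), the sphingosine phosphate receptor gene S1PR1 (-1.36 ± 0.46), ESM1 (-1.40 ± 0.79) and the hyaluronan synthase gene HAS2 (-1.32 ± 1.03), which turned to 0.09 without olive oil replicate 1. ESM1 had -0.20 without olive oil replicate 1, -2.46 without ozonated olive oil replicate 1 and -0.79 without ozonated olive oil replicate 2. OSGIN1 had 0.98 without ozonated olive oil replicate 2, and SMAD6 -0.92 without olive oil replicate 2. None of these passed the test over all genes.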

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

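DESeq2 and limma-voom with the replicate block, and the list tests with the block other than camera, were chosen after the data were seen. The count of 0 genes was 0 with DESeq2 size factors, library totals, upper-quartile factors, 3 other filters, a minimum fold and limma-voom. It was 58 with DESeq2's Wald test, 35 with the edgeR exact test, and 0 to 4 with 1 library left out. With the replicate block it was 841 (468 higher, 373 lower), with DESeq2 and the replicate block 353, all among the 841, and with limma-voom and the replicate block 884, of which 825 were among them. With the block the biological CV was 8.57% against 25.7% without it. Of 93 named genes 70 passed, against 841 of all 14841 tested genes. Many named genes were chosen for a small p or a difference shared by both numbers, so they were bound to pass more often. The 2 libraries of each number deviated together from their group means (correlation 0.672 across genes), but with 2 numbers and no label that ties them to a shared day this remains a hint from the data that the numbers pair the libraries. The 20 lists were 20 with DESeq2 size factors, 21 with a filter of 1 CPM, 21 with the replicate block and 18 to 23 with 1 library left out. They were 0 with an estimated correlation, 0 with fry, 0 with an estimated correlation and the block, and 2 with fry and the block (HIF targets and ferroptosis regulators).

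With 1 library left out, p ranged from 1.98e-20 to 0.112 for the list ATF4 targets (integrated stress response) and from 8.45e-08 to 0.987 for the list cytosolic ribosomal proteins. Log2 fold changes of named genes that turned in sign ranged from -1.14 to 5.54 for CA9, -0.62 to 1.59 for CDKN1A, -1.46 to 1.05 for CHAC1, -0.0898 to 0.47 for CTSB, -1.81 to 2.67 for CXCL8, -3.14 to 0.0909 for HAS2, -0.23 to 0.46 for HMGCS1, -0.15 to 0.0827 for HSPA5, -0.24 to 0.0571 for MCM7, -0.15 to 0.24 for NPM1, -0.21 to 0.89 for NQO1, -0.18 to 0.42 for PSMD2, -0.21 to 0.16 for RRM2, -0.0199 to 0.17 for SPARC and -0.25 to 0.76 for TXNIP. Leaving out a library leaves the numbers unequal between the oils. CXCL8 also turned to 0.34 with limma-voom, 0.14 with the replicate block and 0.35 with DESeq2 and the block; the cause was not tested. No other named gene turned in sign under the other alternatives run. Of genes 2-fold apart in the same direction within both numbers, 40 of 128 had an average log2 CPM of 2 or more.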

Other observations

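Tests of the replicate number, of other cell types and of HIF levels between libraries of the same oil were chosen only after the result was seen. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and the oil in the same fit, 3629 genes differed between the libraries numbered 1 and 2 (1975 lower and 1654 higher in number 2). Among genes picked for their large differences, LCN2, an iron-binding protein of the innate response, lay at 169 and 165 CPM in number 1 and at 0.15 and 0.60 CPM in number 2. The complement gene C3 lay at 425 and 435 CPM against 7.2 and 10.3 CPM, the protease gene MMP9 at 44.0 and 43.0 CPM against 0.30 and 0.60 CPM, IL6 at 36.9 and 15.5 CPM against 0.74 and 1.80 CPM, and the extracellular matrix gene TGFBI at 650 and 682 CPM against 160 and 163 CPM. Of 30 tested NF-kB targets, 23 were lower in number 2 and 0 higher, and of 34 p53 targets 25 were lower and 1 higher. Both lists lost their call with an estimated correlation (adjusted p = 0.732 for each).

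In number 2, targets of ATF4, the factor of amino acid and integrated stress responses, were higher: 38 of 48 were called higher and 1 lower, a list call lost with an estimated correlation (adjusted p = 0.732). The asparagine synthetase gene ASNS lay at 70.8 and 80.8 CPM in number 1 and at 259 and 251 CPM in number 2, and PSAT1, an enzyme of serine synthesis, at 210 and 216 CPM against 548 and 469 CPM. The activin antagonist FST lay at 32.2 and 31.0 CPM against 248 and 254 CPM, and the transcription factor gene TFAP2B at 2.05 and 2.72 CPM against 37.9 and 28.8 CPM. CDKN1A, a p53 target, lay at 374 and 438 CPM in number 1 and at 98.0 and 153 CPM in number 2.

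For the split by replicate number, a per-library correction on GC content and transcript length left 3905 genes called between the numbers against 3629 before it, with 3227 shared, which argues against these trends as the whole cause. Leukocytes in the libraries numbered 1 are argued against, only weakly, by a median of 0.0992 CPM over their marker list there, though CD68 (66.7 and 81.7 CPM against 28.4 and 41.7 CPM) and CTSS (39.0 and 37.4 CPM against 1.08 and 1.06 CPM) were higher in number 1. The bounds of 1 and 10 CPM for both cell types were set with the levels in view, after single genes (PTPRC and KRT5) had been tried first. Keratinocytes are not excluded, since their markers disagree. The 5 abundant keratins had a median excess of 0.828 CPM in number 1, where LCN2 had 167 CPM and KRT6B 45.4 CPM. TP63 had 0 CPM in all 4 libraries, and KRT5 had 0.78 and 0.30 CPM in number 1. But 8 of 11 tested markers were called lower in number 2 and 1 higher, with a list median of -1.55 (camera adjusted p = 3.77e-13, and 0.732 with an estimated correlation). LAMB3 (183 and 175 CPM against 37.7 and 43.4 CPM) and DSC3 were among the higher ones of number 1. FLG went the other way, at 45.1 and 29.1 CPM in number 1 and 89.7 and 61.2 CPM in number 2. What stays open besides is a difference in culture state or passage, library day or stock of cells between the numbers, none of which the labels give, and no biological explanation was tested.

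Genes in several regions had almost no counts. In the MHC region of chromosome 6, 156 of 166 protein-coding genes averaged under 10 counts, and RPS18 (33272075 to 33276511, GRCh38) had 2, 3, 1 and 0 counts. In the leukocyte receptor region of chromosome 19, RPS9 had 16, 7, 14 and 5 counts and TFPT 466, 2, 18 and 0, while the median ribosomal protein gene had 799 CPM. A candidate explanation is that reads matching a second copy in the reference, such as an alternate haplotype, were not counted. Genes elsewhere with a near-identical copy (SMN1, SMN2, EIF3C, EIF3CL, BOLA2 and BOLA2B) had a median of 5.27 CPM against 313 CPM for single-copy EIF3 subunits. They ranged from 0.140 CPM for BOLA2B to 25.6 CPM for EIF3C, the latter far above RPS18 (0.0562 CPM), and only EIF3C and EIF3CL have subunits of the same complex as a comparison, so the explanation stays open, and no biological one was tested.

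For the 128 genes that differed 2-fold in the same direction within both numbers, the GC and length correction left 116 of the 121 with a known GC content (7 lack it), and thinning all libraries to the smallest total left 102 of the 128, which argues against GC content, length or depth as the whole cause. At an average log2 CPM of 2 or more, 40 genes (24 higher, 16 lower) stood where independent differences would give 0.568, a ratio of 70.5. For these 40 genes this argues against counting noise of low genes as the cause. Those of the 128 below that level were not covered. The 8 genes in opposite directions also exceeded the 0.573 of independence, so independence is a poor baseline and 40 against 8 is the plainer contrast. The HIF list differed between the olive oil libraries by a median of -0.44, or 71.8% of its difference between the oils in size, and between the ozonated ones by -0.47, so this difference is balanced over the oils and decides nothing about them. NRF2 targets differed by 0.15 between the olive oil libraries and -0.01 between the ozonated ones, and the actin list by -0.12 and -0.09, against 0.41 and -0.30 between the oils. A response to the ozonated oil stays open as a hypothesis, to be tested in separate cultures of recorded day.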
